A study of Rattus norvegicus with 24 samples.

How the data were processed

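RNA from the livers of 24 rats was measured on 24 Affymetrix arrays, 1 rat per array, in 6 groups of 4. Male RccHan Wistar rats aged 7 to 8 weeks received metformin at 800 mg/kg or the vehicle (0 mg/kg) by gavage daily for 1, 3 or 14 days, per the series' design text and the labels' protocols. That text states 5 animals per group, and 4 arrays per group were analysed here. Animals were housed 2 or 3 to a cage with free access to chow and water, and the cage was not modelled because the labels do not tie rats to cages. RNA came from 70 mg of frozen liver, and 300 ng of total RNA was turned into biotinylated single-stranded cDNA, per the labels' protocols. The hour of necropsy, the feeding state at necropsy, scan dates and hybridisation batches are not given in the sources used here.

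The deposited table holds 1 linear intensity per probe set and array, which the authors made with RMA (background correction, quantile normalization between arrays and a summary per probe set), per the submitters' processing notes. The software and version are not given in the sources used here. The deposited intensities reached 982564 to 994415 per array, above the 65535 steps of a 16-bit scanner, so a change of scale that no source states lies between scanner and table. Fold changes therefore hold on the deposited scale. A linear scale differs from the log2 values that RMA usually gives, so log2 of each deposited intensity was taken before any test. Array data carry no read depth, and the number of arrays limits the precision.

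Of 68842 probe sets, 23446 had 1 gene symbol, 505 had several and 44891 had none in the annotation used here. Symbols were brought up to date through the Entrez identifier for 22077 probe sets, which replaced 1 symbol. Probe sets with several symbols or none entered only an alternative fit. For each of 22093 genes the probe set with the highest mean was used; 1182 genes had more than 1. Genes above 19.475 (4.28 on the log2 scale), the 30th percentile of all values, in at least 4 arrays were tested, which left 19686. Of the tested genes, 785 had a symbol ending in -ps and a number, which marks a pseudogene that can share probes with its parent.

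A linear model with 1 mean per group was fitted over all 24 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that all groups shared 1 estimate of the spread, with 3.51 prior degrees of freedom. The 10 comparisons were metformin against control on each day, the mean of those 3 effects, the differences of the effect between days, and the control animals between days. P values are two-sided and were adjusted over all tested genes by the Benjamini-Hochberg method; genes with an adjusted p under 0.05 were called. Errors beside log2 changes are standard errors of the model, with n = 4 rats per group.

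The 43 gene lists were fixed before the data were examined, as were the model, the threshold, the filter, the rule for named genes and all alternatives but the 1 named as added. They hold 935 places, of which 861 were measured. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 43 lists, and again with a correlation estimated per list and with fry. No list was called with an estimated correlation in any comparison within a day. Calls of list members are also given adjusted over the list alone. The lists include markers of 10 cell types: hepatocyte identity, Kupffer cells and macrophages, stellate cells and fibroblasts, sinusoidal endothelium, cholangiocytes, lymphocytes, neutrophils, erythroid cells and blood, pancreatic acinar cells, and adipocytes. List tests for the differences between days and for the control animals were added after seeing the data, as was a list of genes of transport between the endoplasmic reticulum and the Golgi.

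For each day, the named genes are the 10 called genes with the largest rise and the 10 with the largest fall, up to 4 called members per list with the smallest p, and, called or not, Pck1, G6pc1, Ppargc1a, Cyp7a1, Fasn, Srebf1, Cpt1a, Fgf21, Gdf15, Trib3 and Igfbp1. On a day with fewer than 10 calls the 10 genes with the smallest p are added. For differences between days and for the control animals, the rule takes the 5 called genes with the largest difference each way. Symbols beginning with LOC, RGD, Mir, Snor or AABR were left out. Members of a list that passed over the list alone are named where the list is described.

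The steps were tested on simulated data made from each gene's mean over all arrays and its spread within groups, the same for all groups. In each simulation 50 genes were changed by each of 4 sizes, with independent noise. A log2 change of 0.5 was recovered in 60% of genes on day 1, 44% on day 3 and 34% on day 14, and a log2 change of 1 in 92%, 92% and 100%. The simulations differed only in the group changed and the random draws, so these differences are not a property of the days. False calls were 8 of 196 on day 1, 5 of 185 on day 3 and 8 of 185 on day 14, and 0 of 43 unchanged lists were called by camera on each day. Independent noise holds no correlation between genes, so this cannot show how often camera calls unchanged lists in the real arrays.

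Alternatives were no filter or a filter at the 50th percentile, the mean of a gene's probe sets, every probe set named or not, arrays centred on their median, quantile normalization over again, cyclic loess, an intensity trend with a robust prior, array weights, a fit on the arrays of the compared groups alone, the replicate number as a block, a fold change of at least 1.5, an adjusted p under 0.1, limma's treat at a fold of 1.2, and leaving out each array in turn. A fit without pseudogene symbols was added after seeing the data. Single comparisons of list means used exact permutation tests, for which 4 rats against 4 can give no p below 0.0286. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.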

Results

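Liver transcripts were measured in 24 male rats that received metformin, a biguanide that lowers blood glucose, or its vehicle by daily gavage. Metformin (800 mg/kg) and vehicle groups of 4 rats each were killed after 1, 3 or 14 days, so each day has its own controls. After filtering, 19686 genes were tested on the log2 intensity scale. Median log2 intensity per array lay between 4.80 and 5.11, and arrays of 1 group correlated at r = 0.989 or more across genes. The first principal component held 23.2% of the variance and separated all 8 arrays of day 14 from the others.

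The first comparison addressed the liver's response to 1 day of dosing, and few single genes passed the test. Axin2, a Wnt-induced inhibitor of Wnt signalling, rose 1.78-fold (log2 change 0.83 ± 0.14, adjusted p = 0.0332). Pcbp2, an RNA-binding protein, rose by 0.42 ± 0.06 (adjusted p = 0.00735) and Tmem131, a membrane protein of collagen secretion, by 0.40 ± 0.06 (adjusted p = 0.0332), each on the log2 scale. In each of these 3 genes all 4 metformin rats lay above all 4 controls, an arrangement that chance gives in 2.86% of genes not chosen by their p, counting both directions, and that choosing by p favours. Cpt1a, which brings long-chain fatty acids into mitochondria, differed by 1.22 ± 0.36 (adjusted p = 0.267), and the acyl-CoA thioesterases Acot2 and Acot3 by 1.00 (adjusted p = 0.119) and 0.94 (adjusted p = 0.112), without passing. Other genes with small p that did not pass were Atf5 at 1.00, Mtss1 at 0.81, Pitpnc1 at 0.77, Mboat7 at 0.74 and Cdk2 at 0.59. Of the genes named in any case, Cyp7a1, the first enzyme of bile acid synthesis, differed by -2.48 (adjusted p = 0.331), Igfbp1 by -1.43, Srebf1 by -1.30, Fasn by -1.05 ± 0.53 (adjusted p = 0.636) and G6pc1 by -0.50. Fgf21 differed by 0.52, Ppargc1a by 0.45, Pck1 by 0.09, Trib3 by -0.05 and Gdf15 by -0.33, none passing.

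Camera called 5 gene lists on day 1 at its preset correlation, 0 with an estimated correlation and 0 by fry. Genes of fatty acid and triglyceride synthesis lay lower in 18 of 19 members, with a median log2 change of -0.54 (camera adjusted p = 4.84e-09; adjusted p = 0.554 with an estimated correlation). None of these 19 passed limma's test over all genes and 8 had an unadjusted p under 0.05. Adjusted over the list alone Scd, the stearoyl-CoA desaturase, and Srebf1, a regulator of lipid synthesis, fell by 1.13 and 1.30. Cholesterol synthesis genes had a median of -0.19 (camera adjusted p = 1.56e-04; adjusted p = 0.635 with an estimated correlation). Of these 0 of 21 passed in limma over all genes and 3 had an unadjusted p under 0.05. Pmvk fell by 0.48 adjusted over the list alone. PPARA targets and genes of fatty acid oxidation lay higher, with a median of 0.33 (camera adjusted p = 9.35e-07; adjusted p = 0.554 with an estimated correlation). Of their 32 members 0 passed in limma over all genes and 8 had an unadjusted p under 0.05. Over the list alone 5 rose after adjustment, namely Cpt1a, Acot2, Acot3, Acot1 (0.94) and Ppara (0.98). Heat shock genes had a median of 0.27 (camera adjusted p = 2.95e-07; adjusted p = 0.554 with an estimated correlation). In limma 0 of 15 passed over all genes and 7 had an unadjusted p under 0.05. Adjusted over the list alone 5 rose, the chaperones and co-chaperones Hsph1 (0.95), Bag3 (0.78), Chordc1 (0.68), Hspa8 (0.59) and Stip1 (0.57). Genes of the urea cycle and amino acid breakdown had a median of -0.06 (camera adjusted p = 0.0115; adjusted p = 0.635 with an estimated correlation). In limma 0 of 39 passed over all genes and 3 had an unadjusted p under 0.05. Acmsd fell by 1.23 adjusted over the list alone. No cell type list was called on day 1 (smallest camera adjusted p = 0.452). The median, mean and test differed in sign for the pancreatic acinar, erythroid, hepatocyte identity, lymphocyte and adipocyte markers.

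On day 1 the test called 3 genes, all higher, and 1619 had an unadjusted p under 0.05 against 984 by chance. The count of 3 rested on single arrays. It was 1 without control replicate 1, 2 or 3 or metformin replicate 2, 0 without metformin replicate 3 or 4, 11 without metformin replicate 1 and 14 without control replicate 4. It was also 0 after quantile normalization or cyclic loess, with every probe set, or with the day 1 arrays alone. Centring the arrays left 1 call, as did the replicate block. The 5 called lists became 8 without control replicate 4 or metformin replicate 3 and 10 without metformin replicate 1.

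After 3 days of dosing, rises outnumbered falls by far. Nupr1, a small stress-induced nuclear protein, rose 3.80-fold (log2 change 1.93 ± 0.34, adjusted p = 0.0192), from a log2 intensity of 10.66 ± 0.52 (SD, n = 4) in controls to 12.59 ± 0.33. Other leading rises were Golph3l, a Golgi membrane protein (1.24 ± 0.21, adjusted p = 0.0192), and Sec23b, a coat protein of vesicles leaving the endoplasmic reticulum (1.11 ± 0.20, adjusted p = 0.0192). Beside them stood Arfgap3, a regulator of vesicle coats (1.00 ± 0.18, adjusted p = 0.0239), and Entpd7, a nucleotide-hydrolysing enzyme of internal membranes (1.16 ± 0.22, adjusted p = 0.0269). The rises also held 10 pseudogene symbols of the constitutive chaperone Hspa8, such as Hspa8-ps22 (1.23), Hspa8-ps33 (1.2), Hspa8-ps13 (1.15), Hspa8-ps17 (1.02) and Hspa8-ps6 (1.02). These followed Hspa8 across arrays (lowest r = 0.81) and can share its probes, so they are not separate findings. Hspa8 itself differed by 0.72 (adjusted p = 0.0725). The falls were Loxl1, a cross-linking enzyme of elastic fibres (-0.49 ± 0.10, adjusted p = 0.0292), and Slc8b1, a mitochondrial sodium-calcium exchanger (-0.54 ± 0.11, adjusted p = 0.0429). In all 50 called genes the 4 metformin rats lay beyond all 4 controls, which choosing genes by a small p favours.

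Outside the rule for named genes, and chosen after their values were seen, the calls of day 3 included the tRNA-handling genes Mettl1 (0.94) and Xpot (0.51), the diphthamide enzyme Dph5 (0.85), the mitochondrial factor Mterf1 (0.77 ± 0.10, adjusted p = 0.00404), and the UFMylation ligase Ufl1 (0.76). The same holds for the ribosome assembly genes Heatr1 (0.67), Pwp1 (0.67), Noc3l (0.63) and Utp20 (0.55), and the Golgi and vesicle genes Blzf1 (0.66), Golga3 (0.64), Stx5 (0.57), Scfd1 (0.54) and Cog3 (0.51). Of the genes named in any case, Fasn differed by 0.83 (adjusted p = 0.495), Fgf21 by 0.82 (adjusted p = 0.267), Cyp7a1 by 0.49 and Trib3 by 0.23. Srebf1 differed by -0.21, Cpt1a by -0.35, Pck1 by -0.72 (adjusted p = 0.517), G6pc1 by -0.81 and Igfbp1 by -1.42, and Gdf15 and Ppargc1a by -0.01 each, none passing.

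Stress response groups lay higher on day 3. Of 31 genes of the ATF4 integrated stress response, which links amino acid supply to translation, Nupr1 passed over all genes. Adjusted over the list alone 9 rose: Nupr1, Cars1 (0.90), Nars1 (0.82), Mthfd2 (0.65), Chac1 (0.61), Psph (0.51), Gars1 (0.43), Ddit4 (0.39) and Aars1 (0.36). The list's median was 0.36 (camera adjusted p = 1.84e-10; adjusted p = 0.584 with an estimated correlation). Endoplasmic reticulum chaperones and genes of the unfolded protein response, on 1 list, had a median of 0.25 (camera adjusted p = 8.28e-08, and 0.584 with an estimated correlation). In limma 0 of 20 passed over all genes and 9 had an unadjusted p under 0.05. Adjusted over the list alone 7 rose, Herpud1 (1.22), Creld2 (0.94), Dnajb9 (0.77), Edem1 (0.76), Hyou1 (0.63), Hspa5 (0.35) and Hsp90b1 (0.30). Heat shock genes had a median of 0.25 (camera adjusted p = 3.83e-05; adjusted p = 0.827 with an estimated correlation). In limma 0 of 15 passed over all genes and 7 had an unadjusted p under 0.05. Hsph1 (0.99), Chordc1 (0.74), Hspa8 and Stip1 (0.62) rose adjusted over the list alone. All 38 cell cycle genes lay higher, with a median of 0.30 (camera adjusted p = 8.93e-05; adjusted p = 0.866 with an estimated correlation). However, 0 passed in limma over all genes or adjusted over the list alone and 0 had an unadjusted p under 0.05.

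Kupffer cell markers lay lower on day 3 beside these groups. All 18 Kupffer cell and macrophage markers were lower, with a median of -0.43 (camera adjusted p = 3.83e-05; adjusted p = 0.827 with an estimated correlation). In limma 0 passed over all genes and 4 had an unadjusted p under 0.05. Timd4, a receptor of resident macrophages, fell by 0.37 adjusted over the list alone. The other marker lists were not called. Stellate cells and fibroblasts had a median of -0.16 (adjusted p = 0.087), sinusoidal endothelium -0.16 (adjusted p = 0.134), and cholangiocytes -0.13 (adjusted p = 0.213). Erythroid cells and blood had a median of -0.20 (adjusted p = 0.298), lymphocytes -0.08 (adjusted p = 0.391) and adipocytes -0.18 (adjusted p = 0.456). Neutrophil markers had a median of -0.08 (adjusted p = 0.213) and pancreatic acinar markers of -0.07 (adjusted p = 0.553), both above 0 after quantile normalization or cyclic loess. Hepatocyte identity genes had a median of -0.0017 (adjusted p = 0.825). For the glucocorticoid, NRF2, acute phase, glycolysis and interferon lists the median, mean and test differed in sign on day 3, so no direction is given.

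The test called 50 genes on day 3, 48 higher and 2 lower, with 2687 at an unadjusted p under 0.05 against 984 by chance. The split was 43 of 51 higher after cyclic loess, and the count was 32 in a fit without pseudogene symbols, chosen after seeing the data. The count depended on single arrays. It was 3 without control replicate 1, 20 without control replicate 3, 1 without control replicate 4, 372 without metformin replicate 1, 1 without metformin replicate 2 or 3 and 2 without metformin replicate 4. None of the 12 called named genes kept its call in every such fit (highest adjusted p = 0.184, Slc8b1 without metformin replicate 2). The arrays of day 3 alone gave 0 calls in limma, and the 5 called lists became 8 without control replicate 4.

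After 14 days, Fasn and Acly of fatty acid synthesis were far higher in metformin livers, and Pck1 and 4 metallothioneins far lower. Fasn, the fatty acid synthase, rose 8.5-fold (log2 change 3.09 ± 0.53, adjusted p = 0.00384), from 14.03 ± 1.22 (SD, n = 4) to 17.11 ± 0.59 in log2 intensity. Acly, which makes cytosolic acetyl-CoA, rose 5.45-fold (2.45 ± 0.35, adjusted p = 8.4e-04). Pck1, the cytosolic phosphoenolpyruvate carboxykinase of gluconeogenesis, fell to a level 13.3-fold lower (-3.74 ± 0.49, adjusted p = 5.2e-04), from 17.60 ± 0.39 to 13.86 ± 1.48. Metformin replicate 2 enlarged this fold, at 11.66 against 14.44 to 14.82 in the other metformin rats. The metallothionein Mt2A was 35.7-fold lower (-5.16 ± 0.74, adjusted p = 8.4e-04). The other metallothioneins Mt1m (-6.02 ± 0.86, adjusted p = 8.4e-04), Mt1 (-4.47 ± 0.77, adjusted p = 0.00387) and Mt1f (-4.37, adjusted p = 0.00506) fell with it. Such short, similar transcripts can share probes. For each of these genes all 4 metformin rats lay beyond all 4 controls.

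**Figure D1:**
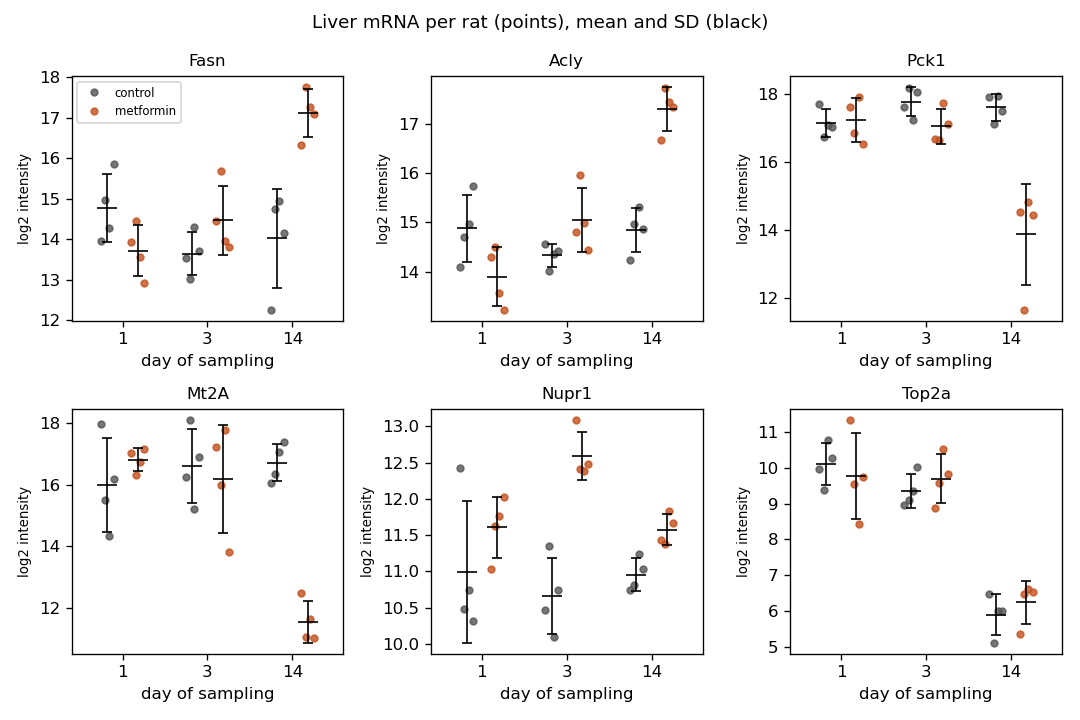
Log2 intensity of Fasn, Acly, Pck1, Mt2A, Nupr1 and Top2a in each rat by day. Points are rats (grey control, orange metformin, 4 per group) and black marks the mean and SD; on day 14 metformin rats lay between 16.33 and 17.76 for Fasn against 12.27 to 14.94 in controls, and between 11.66 and 14.82 for Pck1 against 17.09 to 17.93.

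Some genes of lipid synthesis rose on day 14. Of 19 genes of fatty acid and triglyceride synthesis 9 rose, over all genes and adjusted over the list alone, with a list median of 0.67 (camera adjusted p = 1.11e-09; adjusted p = 0.094 with an estimated correlation). Beside Fasn and Acly these were the elongase Elovl6 (3.60 ± 0.63, adjusted p = 0.00451), malic enzyme Me1 (2.51 ± 0.39, adjusted p = 0.00174), and acetyl-CoA carboxylase Acaca (1.89 ± 0.34, adjusted p = 0.00458). The others were Mid1ip1 (1.31), Thrsp (1.18), Gpam (1.01) and the lipid droplet protein Pnpla3 (4.53 ± 1.01, adjusted p = 0.0162, with 3 of 4 metformin rats above all controls). Srebf1 differed by 0.67 without passing. Of 21 genes of cholesterol synthesis and uptake 6 rose over all genes and 13 adjusted over the list alone, with a median of 0.52 (camera adjusted p = 3.81e-10; adjusted p = 0.0786 with an estimated correlation). The 6 were Mvd (1.28 ± 0.15, adjusted p = 3.3e-04), Msmo1 (1.40 ± 0.25, adjusted p = 0.00502), Lss (1.17), Acat2 (1.13), Hsd17b7 (0.76) and Nsdhl (0.61). In glycolysis Pklr, the liver pyruvate kinase (1.38), and Pfkfb1 (1.16) rose among 21 genes. The list alone gave 4 rises, and the median was 0.10 (camera adjusted p = 0.0384; adjusted p = 0.22 with an estimated correlation). The fructose transporter Slc2a5 (1.88, adjusted p = 0.00726) and the pyruvate dehydrogenase kinase Pdk1 (0.98 ± 0.13, adjusted p = 6.3e-04) also rose. Lipoprotein genes had a median of -0.19 (camera adjusted p = 0.00499; adjusted p = 0.135 with an estimated correlation). Apoa5 (-0.96) and Lcat (-0.27) fell among 20, over all genes and adjusted over the list alone.

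Some genes of glucose production and amino acid breakdown fell on day 14. Gluconeogenesis had 3 falls among 16 genes, Pck1, the serine dehydratase Sds (-2.01 ± 0.42, adjusted p = 0.0126) and the CREB coactivator Crtc2 (-0.55). It had 5 adjusted over the list alone (median -0.11, camera adjusted p = 7.97e-04; adjusted p = 0.0617 with an estimated correlation). G6pc1, the glucose-6-phosphatase, differed by -1.0 (adjusted p = 0.315). Of 19 glucocorticoid response genes 6 fell, Pck1, Mt2A, Mt1, Sds, Irs2 (-1.12 ± 0.29, adjusted p = 0.0361) and Igfbp1 (-3.71 ± 0.99, adjusted p = 0.0414, 3 of 4 metformin rats below all controls). The list had 8 falls adjusted over the list alone (median -0.45, camera adjusted p = 2.61e-06; adjusted p = 0.0627 with an estimated correlation). In insulin, AMPK and FOXO signalling Igfbp1, Sesn2 (-1.32), Irs2 and the insulin receptor substrate Irs1 (-0.65) fell among 22, also adjusted over the list alone (median -0.13, camera adjusted p = 0.00142; adjusted p = 0.0786 with an estimated correlation). The urea cycle and amino acid breakdown had 5 falls among 39, Asl, the argininosuccinate lyase (-0.91 ± 0.14, adjusted p = 0.00134), Mat1a (-0.65 ± 0.11, adjusted p = 0.00384), Sds, the arginine transporter Slc7a2 (-0.62) and Slc38a4 (-0.38). It had 13 falls and 1 rise adjusted over the list alone (median -0.22, camera adjusted p = 1.92e-07; adjusted p = 0.0627 with an estimated correlation). Periportal hepatocyte genes had Pck1 and Sds as falls among 16 and 6 falls adjusted over the list alone (median -0.21, camera adjusted p = 4.12e-06; adjusted p = 0.0627 with an estimated correlation). Pck1, Sds and Igfbp1 stand on several of these lists, which are therefore not independent. Cpt1a fell by 1.67 ± 0.36 (adjusted p = 0.0133) on the log2 scale, while its list, PPARA targets and fatty acid oxidation, was not called (adjusted p = 0.299).

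Some chaperone genes rose on day 14. Heat shock genes had 6 rises among 15, Chordc1 (0.83), Stip1 (0.75, adjusted p = 0.0103), Hspa8 (0.68), Fkbp4 (0.57), Ahsa1 (0.45) and Hspd1 (0.40). For Chordc1 and Hspa8 3 of 4 metformin rats lay above all controls. Adjusted over the list alone 9 heat shock genes rose (median 0.40, camera adjusted p = 1.45e-06, and adjusted p = 0.209 with an estimated correlation). Endoplasmic reticulum chaperones and genes of the unfolded protein response had 5 rises among 20, Creld2 (1.41 ± 0.21, adjusted p = 0.00135), Hyou1 (0.91, adjusted p = 0.0175), Dnajb11 (0.62), Pdia4 (0.60) and Hsp90b1 (0.33). They had 7 adjusted over the list alone (median 0.24, camera adjusted p = 2.93e-04; adjusted p = 0.283 with an estimated correlation). The ATF4 list was not called (adjusted p = 0.0614), with Nars1 (0.69) rising and Sesn2 falling. TCA cycle and respiratory genes had a median of 0.12 (camera adjusted p = 0.00142; adjusted p = 0.283 with an estimated correlation), Pdhb (0.72) being the 1 rise among 34, with 2 adjusted over the list alone. Ndufs1 (0.32, adjusted p = 0.038) and Ndufv2 (0.31, adjusted p = 0.0415) rose among 35 members of complex I, the respiratory complex that metformin is known to inhibit. However, Ndufs1 lost its call in 7 of 8 fits without 1 array and Ndufv2 in 6. The complex I list was not called (adjusted p = 0.674). Fgf21 differed by 0.13, Gdf15 by 0.15, Trib3 by 0.06, Ppargc1a by 0.10 and Cyp7a1 by 0.75, none passing.

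Beside these groups, camera called lists of inflammatory and cell type genes on day 14, but not the list of iron and haem genes (17 measured, adjusted p = 0.949; median, mean and test differing in sign), in which 1 gene rose and 1 fell, over all genes and adjusted over the list alone. Hamp, the iron hormone hepcidin, fell by 2.94 ± 0.70 (adjusted p = 0.0236), and Tfrc, the transferrin receptor, rose by 1.58 ± 0.31 (adjusted p = 0.00876), both on the log2 scale. Hamp was the 1 fall over all genes among 27 acute phase genes, with 5 adjusted over the list alone (median -0.09, camera adjusted p = 4.12e-06; adjusted p = 0.094 with an estimated correlation). Klf6 (-0.50) fell among 18 immediate early genes, with 4 adjusted over the list alone (median -0.30, camera adjusted p = 6.35e-04; adjusted p = 0.209 with an estimated correlation). Ctsl (-0.46) fell among 19 lysosome and autophagy genes, again with 4 (median -0.16, camera adjusted p = 3.47e-04; adjusted p = 0.094 with an estimated correlation). Growth hormone and sex-dimorphic genes had a median of -0.25 (camera adjusted p = 0.00139; adjusted p = 0.0627 with an estimated correlation), with Igfbp1 as the 1 fall among 24 and 2 adjusted over the list alone. Markers of sinusoidal endothelium had a median of -0.21 (camera adjusted p = 7.97e-04; adjusted p = 0.378 with an estimated correlation) and stellate cells and fibroblasts of -0.17 (camera adjusted p = 0.0112; adjusted p = 0.521 with an estimated correlation). Kupffer cells and macrophages had a median of -0.14 (camera adjusted p = 0.0468; adjusted p = 0.69 with an estimated correlation) and adipocytes -0.13 (camera adjusted p = 0.0108; adjusted p = 0.0627 with an estimated correlation). The Kupffer median was -0.45 without control replicate 2 of day 14 (camera adjusted p = 4.41e-06). Its call was lost without control replicate 1, 3 or 4 of that day (-0.07, -0.11 and -0.08; adjusted p = 0.256, 0.282 and 0.183), metformin replicate 1 or 4 (-0.11 and -0.18; adjusted p = 0.28 and 0.0632) or control replicate 2 of day 1 (adjusted p = 0.0508). Hepatocyte identity genes had a median of -0.06 (camera adjusted p = 0.0468; adjusted p = 0.425 with an estimated correlation), which turned to 0.01 after quantile normalization and 0.03 after cyclic loess. In these 5 lists 0 members passed in limma over all genes, with 4, 1, 1, 3 and 2 at an unadjusted p under 0.05 in the order given. Pnpla2 (-0.63), an adipocyte marker that liver also expresses, fell adjusted over the list alone. The lists of cholangiocytes (median -0.10, adjusted p = 0.175), erythroid cells (0.12, adjusted p = 0.674), lymphocytes (-0.01, adjusted p = 0.82), neutrophils (0.07, adjusted p = 0.856) and pancreatic acinar cells (-0.04, adjusted p = 0.74) were not called.

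**Figure D2:**
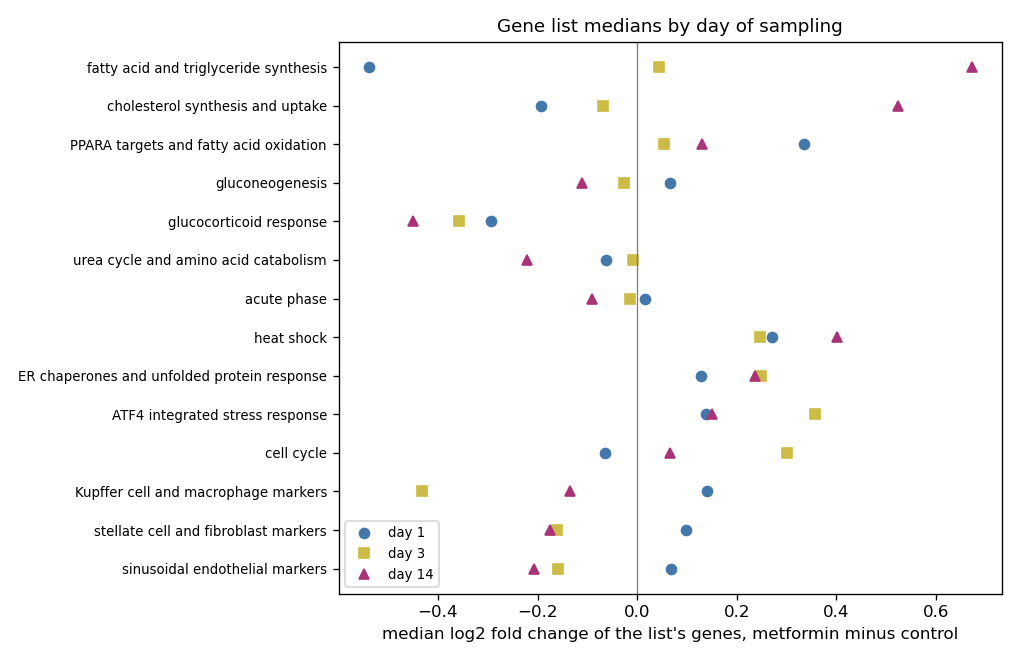
Median log2 fold change, metformin against control, of 14 gene lists on day 1 (circle), day 3 (square) and day 14 (triangle). The median of fatty acid and triglyceride synthesis lay at -0.54 on day 1 and 0.67 on day 14, and that of Kupffer cell markers at -0.43 on day 3.

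The test called 648 genes on day 14, 407 higher and 241 lower, with 3315 at an unadjusted p under 0.05 against 984 by chance. The median size of a called log2 change was 0.49. In 545 of the 648 all 4 metformin rats lay beyond all 4 controls, which choosing genes by a small p favours. In the others the arms overlapped, among them Pnpla3, Igfbp1, Hspa8, Chordc1, Gpam, Pdhb, Plk2 and Slc38a4. The split was 476 higher of 968 without metformin replicate 1 and 240 of 316 without metformin replicate 4, so the majority of rises did not hold without metformin replicate 1. The count was 153 without control replicate 1, 298 without control replicate 4, 344, 427 and 316 without metformin replicate 2, 3 and 4, 225 with every probe set and 48 with the arrays of day 14 alone. Of 55 called named genes 21 kept their call whichever array was left out (among them Fasn, Acly, Elovl6, Me1, Acaca, Mvd, Pck1, Asl, Mat1a and the 4 metallothioneins). Acat2, Stip1, Cpt1a and Sds lost it without control replicate 1 alone (adjusted p = 0.061, 0.0562, 0.0604 and 0.0662). The others lost it without at least 1 array, among them Pnpla3 (up to 0.0812), Hamp (up to 0.0697), Hyou1 (up to 0.0611), Igfbp1 (up to 0.132) and Irs2 (up to 0.155). Camera called 21 gene lists on day 14 at its preset correlation, 0 with an estimated correlation and 18 by fry.

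The overlap between days was strongest for days 3 and 14, which share no arrays. Of the genes called on both, 28 were higher on both days against 0.99 expected of independent lists and Slc8b1 was lower on both (1 against 0.0245), with a fall of -0.81 on day 14 on the log2 scale. Both days came from 1 fit that shared each gene's spread, so the calls are not independent as that expectation assumes. The shared rises include 6 Hspa8 pseudogene symbols, which are not separate findings. With each day fitted on its own arrays no gene was shared, because day 3 then had no call. On day 14, 49 of the 50 genes called on day 3 had the sign they had on day 3. Across all tested genes, which are not independent replicates, the log2 changes of days 3 and 14 correlated at r = 0.36 (rho = 0.30), those of days 1 and 3 at r = 0.05 and those of days 1 and 14 at r = -0.11. No gene was called in the same direction on days 1 and 3 or on days 1 and 14, where limma's calls numbered 3 on day 1 with 1619 at an unadjusted p under 0.05. Pcbp2 rose on day 1 and fell by 0.28 (adjusted p = 0.0116) on day 14. The count of 29 shared by days 3 and 14 was 3, 15 and 1 without control replicate 1, 3 and 4 of day 3, 148, 1, 1 and 2 without metformin replicate 1, 2, 3 and 4 of day 3. It was 14 and 16 without control replicate 1 and 4 of day 14, and 14 and 19 without metformin replicate 2 and 3 of day 14.

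The mean of the 3 daily effects was tested next, which a single day can carry. Of 15 heat shock genes 6 rose over all genes and 12 adjusted over the list alone (median 0.31, camera adjusted p = 7.63e-12; adjusted p = 0.199 with an estimated correlation). Endoplasmic reticulum chaperones and genes of the unfolded protein response had 10 rises among 20 and, adjusted over the list alone, 11 rises and 1 fall. Their median was 0.19 (camera adjusted p = 3.04e-08, and 0.199 with an estimated correlation). The ATF4 list had 8 rises among 31 and 13 adjusted over the list alone (median 0.20, camera adjusted p = 5.46e-08; adjusted p = 0.199 with an estimated correlation), among them the asparagine synthetase Asns (0.87), Atf5 (0.57) and Psph (0.40). Igfbp1 fell by 2.19 and Pck1 fell by 1.46 in this mean; Pck1 differed by 0.09 on day 1 and Mt2A by 0.82, so day 14 carried the falls of these 2 genes. Nupr1 (1.06), Hsph1 (0.99) and Creld2 (0.86) rose and Mt2A (-1.59), the phosphatase Dusp1 (-1.44), Sds (-0.96) and Acmsd (-0.93) fell. These and the ATF4 genes above lie outside the rule for named genes and were chosen after their values were seen. Kupffer markers lay lower in all 18 members (median -0.17, camera adjusted p = 0.00366; adjusted p = 0.589 with an estimated correlation), with 0 passing in limma over all genes and 0 at an unadjusted p under 0.05. Their median was 0.14 on day 1, -0.43 on day 3 and -0.14 on day 14, so day 3 carried most of this mean. The test called 635 genes, 550 higher and 85 lower. The split was 451 of 629 higher after cyclic loess and 416 of 590 after quantile normalization. The count was 422 without control replicate 1 of day 14, 393 without metformin replicate 4 of day 1, and 417 and 420 without metformin replicate 2 and 4 of day 3.

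The difference of the metformin effect between days tested whether the response changed with dosing time. From day 1 to day 14 the effect on some genes of lipid synthesis rose. It rose by 5.33 ± 0.90 for Elovl6 (adjusted p = 0.00612), 4.14 ± 0.75 for Fasn (adjusted p = 0.00807) and 3.43 ± 0.49 for Acly (adjusted p = 0.00239). For Me1 it rose by 3.02 ± 0.55 (adjusted p = 0.00962) and for Pnpla3 by 6.45 ± 1.42 (adjusted p = 0.0254). The effect on Pck1 moved by -3.83 ± 0.69 (adjusted p = 0.00807). That on Mt1m moved by -7.06 ± 1.22 (adjusted p = 0.00667), Mt2A by -5.98 (adjusted p = 0.00667), Mt1 by -5.58 (adjusted p = 0.0133) and Mt1f by -5.44 (adjusted p = 0.0171). In list tests added after seeing the data, 9 of 19 fatty acid and triglyceride genes rose in this difference over all genes and 13 adjusted over the list alone (median 1.55, camera adjusted p = 1.84e-15; adjusted p = 0.0971 with an estimated correlation). Of 21 cholesterol genes 7 rose, and 11 adjusted over the list alone (median 0.66, camera adjusted p = 6.25e-13; adjusted p = 0.108 with an estimated correlation). Between days 14 and 1 the effect differed in 326 genes, 112 more positive and 214 more negative. The split was 144 of 323 more positive after centring, 187 of 393 after quantile normalization and 205 of 407 after cyclic loess.

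Between days 14 and 3 the effect differed in Slc27a3, a fatty acid transport protein, alone (0.76 ± 0.11, adjusted p = 0.0276; 1485 genes at an unadjusted p under 0.05), at a mean log2 intensity near the filter's limit (4.13 to 4.83). That call was lost without control replicate 1 or 4 of day 3 (adjusted p = 0.0501 and 0.104), control replicate 1, 3 or 4 of day 14 (0.0923, 0.102 and 0.0543). It was also lost without metformin replicate 3 of day 3 (0.0775) or metformin replicate 3 or 4 of day 14 (0.0856 and 0.0548). The count of 1 was 0 in these fits, 2 without control or metformin replicate 2 of day 3 or metformin replicate 2 of day 14, 3 without control replicate 2 of day 14, 6 without metformin replicate 4 of day 3 and 5 without metformin replicate 1 of day 14. Between days 3 and 1 limma called 0 genes, with 2102 at an unadjusted p under 0.05, but 8 without control replicate 4 of day 1 and 11 without metformin replicate 1 of day 3. The count of 326 was 178, 203 and 137 without control replicate 1, 2 and 3 of day 1, 144 and 172 without control replicate 1 and 4 of day 14. It was 217, 150 and 142 without metformin replicate 2, 3 and 4 of day 1, 547, 181 and 182 without metformin replicate 1, 3 and 4 of day 14, and 63 with every probe set. Of the 10 named genes only Pnpla3 lost its call in such a fit, up to an adjusted p of 0.0623 without control replicate 1 of day 14.

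**Figure D3:**
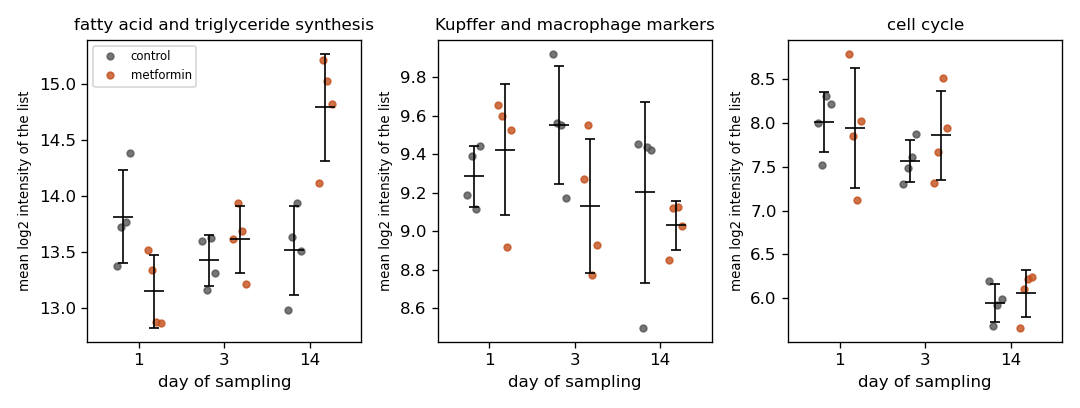
Mean log2 intensity per rat of the fatty acid and triglyceride synthesis, Kupffer cell and macrophage, and cell cycle lists by day. Points are rats (4 per group) with the mean and SD of each group; the cell cycle mean of control rats lay between 7.53 and 8.30 on day 1 and between 5.68 and 6.19 on day 14.

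Control animals were compared across days to see what changed without the drug, and genes of cell division fell steeply by day 14. Against day 1, Mki67, a marker of cycling cells, fell by 4.83 ± 0.56 (adjusted p = 7.0e-05) and Top2a, the topoisomerase of replication and mitosis, fell by 4.21 ± 0.47 (adjusted p = 5.7e-05). The spindle gene Ckap2 fell by 3.99 and the ribonucleotide reductase Rrm2 fell by 5.95 ± 0.69, and Rrm2l1 fell by 6.21, all on the log2 scale. All 38 cell cycle genes were lower. Of these 34 fell over all genes and 37 adjusted over the list alone, with a median of -2.05 (camera adjusted p = 1.81e-87; adjusted p = 0.0108 with an estimated correlation). Genes that rose included Sdr16c6 (2.22), Marveld1 (1.75), Sds (1.66), the pyruvate dehydrogenase kinase Pdk4 (1.63) and malic enzyme Me3 (1.16). The drug efflux pumps Abcb1b (-2.76) and Abcb1a (-1.67) fell among 10 transporters, with 4 adjusted over the list alone (median -0.14, camera adjusted p = 7.57e-04; adjusted p = 0.0177 with an estimated correlation). Of 21 clock genes 5 fell, Usp2 (-1.21), Per1 (-1.06), Wee1 (-0.84), Hlf (-0.80) and Dbp (-0.48). Adjusted over the list alone 9 fell and 3 rose (median -0.17, camera adjusted p = 1.79e-04; adjusted p = 0.0993 with an estimated correlation).

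Against day 3, the same direction held for the cell cycle list, with 26 of 38 falling over all genes and 35 adjusted over the list alone (median -1.60, camera adjusted p = 1.86e-58; adjusted p = 0.0231 with an estimated correlation). It was led by Rrm2l1 (-5.25), Rrm2 (-4.91), Mki67 (-4.03), Ckap2 (-3.61) and Top2a (-3.46). Genes of the urea cycle and amino acid breakdown had 5 rises among 39, Sds (1.77), Acmsd (1.37), Hal (0.96), Slc7a2 (0.80) and Ass1 (0.45). It had 15 adjusted over the list alone (median 0.27, camera adjusted p = 7.44e-11; adjusted p = 0.0231 with an estimated correlation). Sdr16c6 (2.48), Me3 (1.24) and Kctd20-ps1 (1.07) also rose. Limma called 359 genes between days 14 and 1, 51 higher and 308 lower. It called 175 between days 14 and 3, 26 higher and 149 lower, a split that was 42 of 155 higher after centring the arrays. The 175 became 115 and 98 without control replicate 2 and 3 of day 3 and 94 and 99 without control replicate 2 and 4 of day 14. The call of Sds was lost in 7 of 8 such fits (up to adjusted p = 0.174 against day 1, without control replicate 1 of day 14, and 0.159 against day 3, without control replicate 3 of day 3). Acmsd lost its call against day 3 in 6 of 8 (up to adjusted p = 0.105, without control replicate 2 of day 14). Sdr16c6 against day 1 (adjusted p = 0.055, without control replicate 2 of day 14) and Kctd20-ps1 against day 3 (adjusted p = 0.05, without control replicate 3 of day 3) each lost it in 1. Between days 3 and 1 limma called 0 genes, with 927 at an unadjusted p under 0.05. All 38 cell cycle genes were lower there (median -0.46; adjusted p = 0.712 with an estimated correlation).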

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

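The tests of control drift and of time of day for the lipid genes, of other cell types and of blood for the Kupffer markers, and both tests of the cell cycle genes were chosen only after those results were seen. The exact tests of the pooled lipid list means were not set beforehand either. The other tests of explanations in this part were set beforehand.

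The 40 measured genes of fatty acid, triglyceride and cholesterol synthesis lay lower on average in metformin livers on day 1 and higher on day 14. Their mean differed by -0.42 and 0.90, with all 4 metformin rats below, then above, all 4 controls. The exact permutation p was 0.0286 on each day, the smallest that 4 against 4 can give. Camera had already called both pooled lists in these directions in the same arrays, so these p values repeat that choice and are no separate support. With an estimated correlation camera called neither list on either day. Drift of the controls is argued against as the main cause of the difference between the effects of day 14 and day 1. Their change of -0.18 between the days (SE 0.17, exact p = 0.343) made up 13.7% (SE 12.9) of that difference of 1.32. The metformin arm moved by 1.14 (exact p = 0.0286). This share does not bear on the day 1 difference of -0.42 alone. The control mean of the fatty acid and triglyceride list was 13.81 on day 1, 13.42 on day 3 and 13.52 on day 14. High controls on day 1 therefore stay open for that difference. A different hour of sampling between the arms stays open, since the 21 clock genes' median absolute change of 0.18 on day 14 lay at percentile 93.9 of 10000 random lists matched on expression (90.7 on day 1), short of the 95 set for calling it a cause and far from excluding it. Feeding that differed between animals also stays open. Within groups the lipid list mean and the mean of Pck1, Igfbp1 and Cpt1a correlated at r = -0.185 over 24 arrays (permutation p = 0.402, 100000 permutations). The rank correlation rho was -0.21 (permutation p = 0.363), and r was -0.11 without the 2 farthest arrays. The r of -0.185 lay just past the bound set beforehand against this explanation but within its standard error of 0.234. The need to pass the bound by more than that error was added after the value was seen. Each group's mean was subtracted first, so the test cannot see feeding that differed between metformin and control rats. Such a difference between the arms was not tested. That the effect differed between days 14 and 1 was tested gene by gene, and a response to metformin that turns with days of dosing may account for it as a hypothesis that stays open beside these.

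Kupffer cell and macrophage markers lay lower in metformin livers on day 3, by -0.42 in the list mean, with 2 of 4 metformin rats below all controls (exact p = 0.143). Scaling the arrays again did not remove the fall. The list median of -0.43 was -0.48 after cyclic loess and -0.478 after quantile normalization, with 18 of 18 markers lower under both. The deposited values were already quantile normalized, and the median over all genes moved only from -0.031 to -0.0041 and -0.0047. These steps could hardly have removed the fall, so they are a weak test of scaling between arrays. A lower share of all cell types other than hepatocytes stays open: the 47 stellate, endothelial and bile duct markers differed by -0.16 (exact p = 0.0571), and the Kupffer mean less theirs by -0.260 (exact p = 0.286). Less blood in the tissue stays open too, with blood markers at -0.19 (exact p = 0.371) and the Kupffer mean less theirs at -0.228 (exact p = 0.4). Control rats of day 3 lay above those of day 1 (median 0.19, camera adjusted p = 0.00111; 0.712 with an estimated correlation) and of day 14 (median of day 14 minus day 3 -0.27, camera adjusted p = 1.63e-04; 0.464 with an estimated correlation), but the first median was 0.11 without replicate 1 of day 3 (adjusted p = 0.0827) or replicate 3 of day 1, and the second -0.08 without replicate 2 of day 14 (adjusted p = 0.285), -0.18 without replicate 1 and -0.42 without replicate 4 of day 3, so high controls on day 3 and a loss of Kupffer cells under metformin both stay open.

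Cell cycle genes fell between day 1 and day 14 in control rats (median -2.05, exact p = 0.0286) and in metformin rats (median -1.97, exact p = 0.0286). Other genes did not shift with them between the days in control rats. The list median lay at percentile 0 of 10000 random lists matched on expression, whose medians ran from -0.12 to 0.09. Camera had already set the list against all other genes in the same arrays, and the median change over all genes was 0.019. The outcome was therefore fixed beforehand and is no separate test of a shift of whole arrays. Fewer dividing blood cells in the tissue stay open: 46 erythroid, lymphocyte and neutrophil markers had a median change of 0.0405 (bootstrap SE 0.018), with Cd74 (mean log2 intensity 9.68), Alas2 (8.61), Ptprc (7.89), Hbb (7.51), Slc4a1 (6.90), Epb42 (5.53) and Ahsp (5.40) at -0.23, -0.12, -0.01, -0.08, -0.36, -0.31 and 0.19, but 27 were higher and 19 lower and markers of all blood cells would hide a small dividing share, so the test, whose bound had been passed, was set aside as undecided after its value was seen. The age of the rats and the number of gavages, which the design ties to the day, could lower liver cell division and stay open untested. A batch of arrays or of animals per day cannot be told apart from the day, because each control group lies on 1 day.

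Other splits of the same arrays show how often another grouping called as many genes or lists. The real grouping called the most genes on day 3 (50 against at most 8 in any other split, 1 of 35 splits as large) and day 14 (648 against 137, 1 of 35). It also did for the control animals between days 14 and 1 (359 against 4, 1 of 35) and 14 and 3 (175 against 1, 1 of 35). With 100 random splits it did for the mean of the days (635 against 3, 1 of 100) and the effect's change from day 1 to day 14 (326 against 91, 1 of 100). Those splits exchange metformin and control within each day, so a drug effect on day 14 alone could make the real grouping the largest. They therefore cannot show whether the effect changed between days. A share of 1 of 35 is the smallest that 35 splits can give. No adjustment over the several tests was made, so chance is not excluded by these shares. Other splits called as many for the genes of day 1 (3 against 4, 2 of 35) and the effect's change from day 3 to day 14 (1 against 90, 7 of 100). The same holds for the lists called on day 1 (5 against 13, 29 of 35), day 3 (5 against 11, 24 of 35) and day 14 (21 against 23, 2 of 35). The real count was 0 for the effect's change from day 1 to day 3 (other splits up to 11) and the controls between days 3 and 1 (up to 2). Every split reaches a count of 0, so these 2 comparisons cannot be judged this way. Splits that called 90 genes where the real one called 1, and 11 where it called 0, point to a structure of the samples, to which the drug effects themselves may contribute because these splits relabel arrays within the days; this was not tested.

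The effect of metformin differed between days 14 and 1 by limma's test of the difference in 326 genes. Among the named genes of a single day, more positive on day 14 were Pnpla3 (6.45), Elovl6 (5.33), Fasn (4.14), Acly (3.43), Me1 (3.02), Slc2a5 (2.29), Acaca (2.05), Srebf1 (1.97), Tfrc (1.95), Msmo1 (1.75), Acat2 (1.5), Mvd (1.47), Pdk1 (1.25), Creld2 (1.17) and Nsdhl (0.75). More negative were Mt1m (-7.06), Mt2A (-5.98), Mt1 (-5.58), Mt1f (-5.44), Pck1 (-3.83), Cpt1a (-2.90), Osgin1 (-2.34), Mboat7 (-1.35), Irs1 (-1.30), Asl (-1.10), Pitpnc1 (-0.91), Slc8b1 (-0.89), Cdk2 (-0.85), Pcbp2 (-0.70), Crtc2 (-0.67), Mat1a (-0.65), Ctsl (-0.59), Tmem131 (-0.51), Tef (-0.45) and Lcat (-0.43). Between days 14 and 3 it differed in 1 gene, Slc27a3 (0.76).

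Of 331 groups of 4 rats tested for a rat far from the others, 27 had one by Dixon's ratio of gap to range, where chance gives about 1 in 20 groups, or 16.55. On day 1 these were Mboat7 in metformin replicate 1 (lowest, 0.871) and Fgf21 in control replicate 1 (highest, 0.847). On day 3 metformin replicate 1 was highest for Nupr1 (0.861) and lowest for Golph3l (0.931), Hspa8-ps13 (0.849) and Hspa8-ps17 (0.868). Metformin replicate 3 of that day was highest for the ATF4 list mean (0.898). Control replicate 4 was lowest for Arfgap3 (0.924) and the mean of the endoplasmic reticulum chaperone and unfolded protein response list (0.85), and highest for Me3 (0.849). Control replicate 2 was lowest for Cyp7a1 (0.92). On day 14 metformin replicate 1 was lowest for Pnpla3 (0.957), Me1 (0.865) and Stip1 (0.886), metformin replicate 2 was highest for Tfrc (0.965) and Igfbp1 (0.83) and lowest for Pck1 (0.878), and metformin replicate 4 was lowest for Asl (0.851) and the acute phase mean (0.85). In controls of day 14, replicate 1 was lowest for Srebf1 (0.835) and highest for Ckap2 (0.837), and replicate 2 highest for Crtc2 (0.904) and lowest for the Kupffer mean (0.969). Replicate 3 of these controls was highest for Hspd1 (0.847) and the mean of the endoplasmic reticulum chaperone and unfolded protein response list (0.895). It was lowest for Slc38a4 (0.873), and replicate 4 was lowest for Mvd (0.841).

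Probe sets without 1 gene symbol, which no comparison of genes used, also differed between metformin and control. Among 54323 probe sets tested, of which 33543 had no single symbol, 11 of the latter were called on day 3 (9 higher, 2 lower) and 49 on day 14 (34 higher, 15 lower).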

How the results depend on the processing

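The fit without pseudogene symbols was chosen after seeing the data; the other alternatives were planned. Over 137 results for named genes, 1506 values under the planned and added alternatives kept direction and side of the threshold in 1347 cases, fell short of it in 150, newly passed it in 6 and reversed in 3; over 1184 fits without 1 array these numbers were 892, 271, 5 and 16. Changes near a log2 size of 0.5 were recovered in 34% to 60% of simulated genes, depending on the random draw, so small effects limit every count here. Dim signals near the filter's limit carry less information, and no detection call was used. Except where fewer arrays or genes entered the fit or the threshold itself moved, the cause of a change was not tested.

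Counts of called genes that moved by over 1.5 times are grouped by setting. With an adjusted p under 0.1 the counts were 198 on day 3, 1158 on day 14, 1098 for the mean of the days, 4 for the effect from day 1 to day 3, 663 from day 1 to day 14 and 2 from day 3 to day 14, 298 for the controls from day 3 to day 14, and 106 genes shared by days 3 and 14 and 1 by days 1 and 14. Array weights gave 27 on day 1, 267 on day 3, 1016 for the mean, 13, 610 and 3 for the same 3 changes of the effect, 320 for the controls from day 3 to day 14, and overlaps of 112 and 1. A fold of at least 1.5 left 1, 30 and 226 on the 3 days, 58 for the mean and an overlap of 16. Limma's treat at 1.2 left 0, 0 and 27 on the days, 0 for the mean, 21 and 0 for the effect from day 1 and from day 3 to day 14, and 129 and 51 for the controls from day 1 and day 3 to day 14. With every probe set the days gave 0, 27 and 225, the mean 282, the effect 63 and 0, and the overlap 7. The compared arrays alone gave 0, 0 and 48, the effect 158 and 0, and the overlap 0. Centring gave 1 on day 1 and 1 for the effect from day 1 to day 3, quantile normalization 0 and 4, and cyclic loess 0 and 3, with 2 from day 3 to day 14. The filter at the 50th percentile gave 4 and 0 for the effect from day 1 to day 3 and from day 3 to day 14, the intensity trend with a robust prior 1 and 0, and the fit without pseudogene symbols 32 on day 3.

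Lists called with an estimated correlation were 0 on each day. Fry called 0 on days 1 and 3 and 18 on day 14, where camera called 21 at its preset correlation. On day 3 quantile normalization and cyclic loess gave 8 each. Of 121 calls of a list in any of the 10 comparisons, 2 had a median that turned sign under another scaling. Gdf15 on day 3, at -0.0067, turned to 0.0173 with array weights, 0.0171 after cyclic loess and 0.0062 after quantile normalization.

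The replicate numbers were shared by the groups, but same-numbered arrays did not deviate together (r from -0.05 to 0.09, 0 of 12 pairs over 0.1, 2 of 12 closest to their own number), so the numbers were not taken as a pairing. With the replicate block the counts were 1 on day 1, 208 for the effect from day 1 to day 14 and 0 from day 3 to day 14; other counts stayed within 1.5 times.

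Without 1 array the counts ranged from 0 to 14 on day 1, 1 to 372 on day 3, 153 to 968 on day 14, 393 to 945 for the mean, 0 to 11, 137 to 547 and 0 to 6 for the effect from day 1 to day 3, day 1 to day 14 and day 3 to day 14, and 0 to 0, 243 to 348 and 94 to 142 for the controls in the same order. Called lists ranged from 4 to 10, 4 to 8 and 17 to 20 on the 3 days, and overlaps from 1 to 148 for days 3 and 14, 0 to 1 for days 1 and 14 and 0 to 0 for days 1 and 3. Values that reversed, none of them called, are given with their range without 1 array. Pck1 on day 1 ran from -0.135 to 0.325 and was negative without control replicate 2 and metformin replicates 1 and 3. Trib3 on day 1 ran from -0.244 to 0.117, positive without control replicate 1. Gdf15 on day 3 ran from -0.089 to 0.0604, positive without control replicates 3 and 4 and metformin replicates 2 and 3. Cyp7a1 on day 3 ran from -0.162 to 1.01, negative without control replicate 2. Ppargc1a ran from -0.164 to 0.171 on day 3, positive without control replicates 1 and 2 and metformin replicates 2 and 4, and from -0.0943 to 0.310 on day 14, negative without control replicate 2 and metformin replicate 3. Fgf21 on day 14 ran from -0.0365 to 0.285, negative without metformin replicate 2.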

Other observations

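The list tests between days in control rats were chosen only after the data were seen, and the test of secretory transport genes after the leading genes of day 3 were seen but before its own result was. Single genes named in this part were chosen after their values were seen, except where named before.

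Other groups of genes also differed between control rats of day 14 and day 3. NRF2 targets had 3 falls among 27 genes, the glutathione genes Gclc (-0.89) and Gsr (-0.54) and the exporter Abcc4 (-0.41), and 6 adjusted over the list alone (median -0.18, camera adjusted p = 6.78e-05; adjusted p = 0.0899 with an estimated correlation). PPARA targets and fatty acid oxidation genes lay lower in 29 of 32 members (median -0.39, camera adjusted p = 1.23e-09; adjusted p = 0.119 with an estimated correlation), with 0 passing in limma over all genes, 15 at an unadjusted p under 0.05, and 9 falls and 1 rise adjusted over the list alone, among them Crat (-0.96), Hadha (-0.45) and Pdk4 (0.97). Of the CAR and PXR targets Abcb1a (-1.32) fell, the 1 of 17 over all genes, and 3 adjusted over the list alone (median -0.32, camera adjusted p = 7.84e-05; adjusted p = 0.083 with an estimated correlation).

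Lists that were not called on day 14 also held genes that changed. In the p53 list, which was not called (adjusted p = 0.15), Plk2 rose by 1.48 (adjusted p = 0.049), the 1 rise of 15 over all genes, with 2 adjusted over the list alone. Hypoxia response genes went both ways, Pdk1 rising and Kdm3a falling by 0.47 (adjusted p = 0.0063), and the list was not called (adjusted p = 0.949). NRF2 targets, likewise not called (adjusted p = 0.678), had rises of Me1 and of Nfe2l2 (0.42), the gene of NRF2 itself, and a fall of Osgin1 (-1.54); adjusted over the list alone 5 rose and 3 fell. The kinase gene Sgk2 rose by 2.11 (adjusted p = 0.00444), on no list. Without 1 array in turn, Plk2 and Osgin1 lost their calls in 6 of 8 fits and Nfe2l2 (adjusted p = 0.0498) in 7. Pdk1, Kdm3a, Me1 and Sgk2 kept theirs in all 8.

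A hypothesis drawn from the leading genes of day 3 is that metformin raised genes of transport between the endoplasmic reticulum and the Golgi as a class. A list of 65 such genes, of which 62 were measured, left out Golph3l, Sec23b, Arfgap3, Golga3, Stx5, Scfd1 and Blzf1, but held Cog3, which had been called and was its 1 call over all genes, with 20 adjusted over the list alone. On day 3 the list mean differed by 0.18 with 3 of 4 metformin rats above all controls (exact permutation p = 0.0857), so the test set for it did not decide. Of the 62 members 48 were higher, and camera gave p = 8.8e-13, or p = 0.00679 with an estimated correlation. Unlike those of the other lists, the camera p values of this list were not adjusted. Both tests of day 3 used the arrays whose leading genes prompted the list, so neither is separate support. On day 14 the mean differed by 0.14 (exact permutation p = 0.0286, the smallest possible), with 7 members rising and 1 falling over all genes and 15 changing adjusted over the list alone, while camera gave p = 5.18e-06, or p = 0.0671 with an estimated correlation. On day 1, for which no exact test was set, 40 members were higher and camera gave p = 0.108, or p = 0.501 with an estimated correlation. A class-wide rise may be present from day 3 on, which more animals per group would be needed to decide.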
